A study of Homo sapiens with 6 samples.

How the data were processed

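The values analysed were those of the series' deposited table of 6 single-colour oligonucleotide arrays, 1 per sample, hybridised with biotin-labelled cDNA made from total RNA, per the labels' protocols. Cells were harvested near confluence, per the labels. The authors' deposited values were taken as log2 signals per probe set. Neither the labels nor the table's header names the log base, so it was read from the values, which run from 1.88 to 14.64 with array medians of 5.31 to 5.38. A natural or base 10 logarithm would put the brightest signals above a 16-bit scanner's range. All folds and log2 differences rest on that reading. The background correction, normalization and summarisation of probes are not given in the sources used here. The submitters' processing notes name limma, without a version or the step it served. The arrays' distributions were close and not identical, and the values were not centred per probe set. Scanner output was not used here.

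Probe sets were named through GEO's platform annotation, with symbols checked by Entrez ID in a RefSeq gene table of assembly GRCh38.p14, which held all 15835 named probe sets and changed 0 symbols. Of 46255 probe sets, 15835 (34.23%) had 1 gene symbol, 0 had several and 30420 were unnamed here. Control probes could not be told from other unnamed probe sets, so all 46255 entered the count over probe sets. There were 14812 genes, 11911 of them protein-coding. The 651 genes with several named probe sets were each represented by the probe set with the highest mean over the 6 arrays. The 6 values of 1014 probe sets repeated those of an earlier probe set, and 7 named probe sets shared all values with a probe set of another gene. The genome build behind the array is not given in the sources used here, so no coordinates are given, and the RefSeq table served only for names and for the order of genes along chromosomes.

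Samples were grouped by their labels into 3 arrays labelled sgCtrl and 3 labelled sgNSD3, which the labels call biological replicates. The comparison was the difference of arrays labelled sgNSD3 minus arrays labelled sgCtrl on log2 values, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) and Benjamini-Hochberg adjustment. Genes passed at an adjusted p under 0.05, with no filter on dim probe sets. Folds are 2 to the power of the log2 difference. SE is that of the moderated fit, and SD is over the 3 arrays of a group. The terms rose, fell, higher and lower describe members that passed over all genes.

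Before the data were examined, 43 gene lists with 1170 entries were fixed, of which 704 entries were measured. The list of core and linker histones had 0 measured members. The other 42 lists, each with at least 5 measured members, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 42 lists. An estimated correlation and fry were alternatives. The genes named were fixed by a rule at the same time. They are NSD3, the 12 largest rises and 12 largest falls among genes that passed and whose groups did not overlap, and up to 4 members of each list with the smallest p. XIST and Y-linked genes are never named. Genes named outside this rule are said to be so.

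Alternatives were leaving out the dimmest 25% or 50% of probe sets, quantile normalization, median centring, a trended and robust variance, array weights, the replicate number as a block, leaving out each array, the mean of a gene's probe sets, an adjusted p under 0.01, a fold of at least 2, and a test without moderation. After the data were seen, 1 more was added: for the 8502 genes with a mean signal of at least 6, the median log2 difference of the 24 nearest such genes was subtracted from the arrays labelled sgNSD3. The fits were tested on simulated data with the real genes' means. Spreads were drawn at random from limma's fitted prior, and noise was independent between genes. The simulation therefore does not show how often lists of correlated genes are called wrongly. Of 200 seeded genes among 14812, 79% of those changed 1.5-fold and 97% of those changed 2-fold were called, 0 with the wrong sign. Another 14 unchanged genes were called, 7.37% of the calls. A seeded list was called in the right direction and 0 lists without shared members were. In 8502 simulated genes, the correlation of neighbours was 0.006 without seeded structure and 0.495 with it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Arrays have no read depth, and the table holds no detection calls, so a low signal was not classed as absent. Where a named gene's mean lay below the 25th percentile of all probe sets in every array of 1 group, its fold was taken against the mean of those percentiles and is written as a bound.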

Results

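Total RNA of U2-OS cells, an established human osteosarcoma line, was measured on 6 oligonucleotide arrays, 1 per sample, with biotin-labelled cDNA. Per the labels, 3 arrays came from cells with a non-targeting CRISPR guide (sgCtrl) and 3 from cells with a guide against NSD3 (sgNSD3), which the labels call knockdown cells, each a biological replicate. NSD3 encodes a histone methyltransferase of the NSD family, which acts on lysine 36 of histone H3. The single comparison asked how transcript levels differ when NSD3 is targeted in osteosarcoma cells. The median signal lay between 5.31 and 5.38 on the log2 scale over the 6 arrays. Pearson's r across probe sets was 0.992 to 0.994 within groups and 0.983 to 0.987 between them, and no array repeated another. The number of arrays, 3 per group, limits the precision. How the replicates of a group were derived was not analysed here, and the limma p-values measure the spread between arrays within groups. If the arrays of a group share 1 derived cell population, an effect of the guide cannot be told apart from another difference between the populations.

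NSD3, the targeted gene, was higher in the arrays labelled sgNSD3, against the knockdown that the labels name. Probe set 17076372 read 7.36 ± 0.05 (SD, n = 3) in the arrays labelled sgCtrl and 9.82 ± 0.04 (SD, n = 3) in those labelled sgNSD3. This was a log2 difference of 2.46 (SE 0.059), or 5.50-fold higher, with a limma adjusted p of 1.66e-06 over genes. The other NSD3 probe set, 17068061, read 6.06 ± 0.24 and 8.94 ± 0.16 (SD, n = 3 each), 7.34-fold higher, with a limma adjusted p of 9.06e-05 over probe sets. In the first probe set the lowest array labelled sgNSD3 lay 2.39 log2 units above the highest labelled sgCtrl, and in the second 2.56. An exact permutation test of 3 arrays against 3 cannot go below 0.1 and was not used. Where on the NSD3 transcript these probes lie was not analysed here, and arrays do not measure the protein. Because the target went against the label, every direction that follows is stated by label, as the arrays labelled sgNSD3 against the arrays labelled sgCtrl, and would turn if the labels were exchanged.

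**Figure D1:**
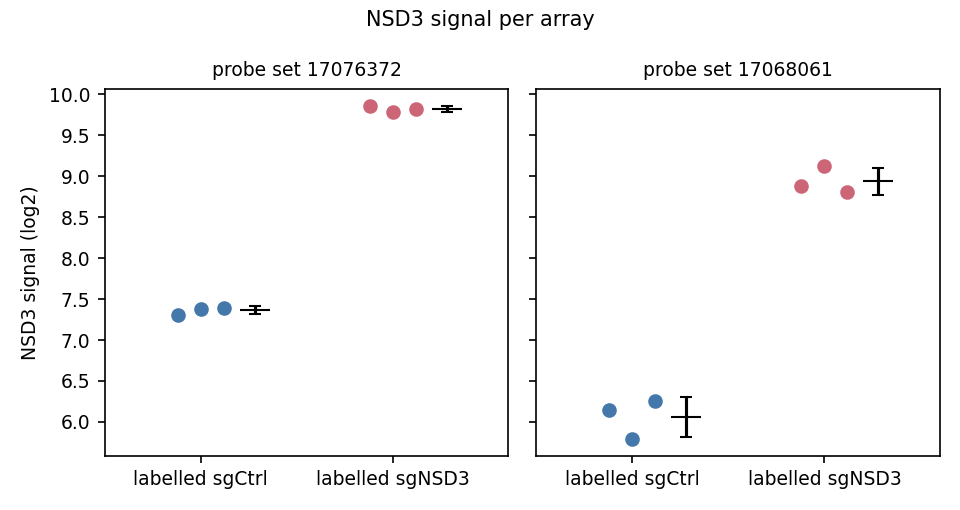
NSD3 signal on the log2 scale (y axis) in each array of the 2 labelled groups (x axis), for both NSD3 probe sets. Points are arrays, and the black bar with whiskers is the mean ± SD of 3 arrays. In both probe sets all 3 arrays labelled sgNSD3 lie above all 3 labelled sgCtrl, by at least 2.39 log2 units.

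Among rises with both groups above the dimmest 25% of signals, the largest in the arrays labelled sgNSD3 was that of SRGN, which encodes serglycin, a proteoglycan of secretory granules. It went from 5.27 ± 0.01 to 10.27 ± 0.05 (SD, n = 3 each), 32.0-fold higher (log2 difference 5.00, SE 0.057, limma adjusted p = 2.67e-08). The hair follicle keratin KRT75 was 8.41-fold higher, the annexin ANXA10 7.69-fold, the zinc finger gene ZNF597 6.84-fold and the long non-coding RNA UCA1 4.97-fold. Next came the zinc finger genes ZFP30 and ZNF542P, at 4.38-fold and 4.06-fold higher, and CTAGE1, at 4.37-fold. The Notch ligand JAG1 rose 3.84-fold and KLB, the co-receptor for endocrine fibroblast growth factors, 3.78-fold. AADACP1 rose from 3.03 to 4.95. The former lies below the 25th percentile of the arrays labelled sgCtrl (3.90 to 3.93), where background limits how low a signal can read, so its fold is given as a bound, at least 2.05-fold against that percentile. JAG1 lay in a stretch of neighbouring genes that were higher together, and its 24 nearest genes had a median log2 difference of 0.30.

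GTSF1, a gene of the germline piRNA pathway, fell from 8.93 ± 0.06 to 3.79 ± 0.08 (SD, n = 3 each) in the arrays labelled sgNSD3 (limma adjusted p = 4.15e-08). The collagenase MMP13 fell to 3.52 and the protocadherin PCDHB15 to 3.78. All 3 ended below the 25th percentile of those arrays (3.91 to 3.96), where background limits how far a signal can fall. Their folds are therefore bounds against that percentile, at least 31.7-fold lower for GTSF1, 10.96-fold for MMP13 and 5.78-fold for PCDHB15, and have no order. Among falls measured above it in both groups, ARHGEF10 was 7.98-fold lower and CCBE1, needed for lymphatic growth, 5.94-fold. Other protocadherin beta cluster members fell too, the pseudogene PCDHB18P 5.49-fold and PCDHB6 4.90-fold. ZSCAN12P1 was 5.43-fold lower, the calcium buffer PVALB 5.33-fold, LINC01446 5.11-fold, HSD17B14 4.90-fold and the chemokine CXCL14 4.73-fold. The 24 nearest genes of ARHGEF10 had a median log2 difference of -0.53.

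Of 14812 genes with a named probe set, 3580 (24.2%) passed a limma adjusted p of 0.05, with 1646 higher and 1934 lower in the arrays labelled sgNSD3. All 3580 had groups of arrays that did not overlap. Such separation held for 6088 genes (41.1%), where chance gives 10%. At a fold of 1.5 or more, 873 genes passed, of which 325 were higher and 548 lower, and at a fold of 2 or more 217 passed, of which 74 were higher and 143 lower. The median log2 difference over all genes was 0.02. Over all 46255 probe sets, named or not, 5288 passed, with 2291 higher and 2997 lower. Unnamed probe sets made up 2696 of these. The count over probe sets fell to 3238 without sgCtrl replicate 1, 3169 without sgCtrl replicate 2, 3342 without sgCtrl replicate 3 and 3132 without sgNSD3 replicate 1.

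Among 42 gene lists fixed before the data were examined and tested, 10 stood apart from the other genes by camera with a preset correlation, 6 of them higher and 4 lower in the arrays labelled sgNSD3. With a correlation estimated from the arrays, none of the 10 calls held: camera then called 0 lists, its lowest adjusted p was 0.279, and 5 lists had an unadjusted p under 0.05. The estimate lay below the preset 0.01 for p53 targets (-0.022), MYC targets (-0.024), apoptosis regulators (-0.014), matrix proteases (-0.047) and NF-kB genes (-0.006). A larger correlation therefore cannot account for the loss of those calls. In the other called lists it ran from 0.040 (TGF-beta and BMP targets) to 0.12 (G2/M and mitosis). By fry, which asks whether a list's genes move one way and does not compare them with other genes, 24 lists passed. Member counts in the paragraphs that follow stand against 24.2% of all genes and 27.1% of protein-coding genes that passed. A list whose share of passing members is near or below these is not set apart by its count.

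The list with the smallest p was that of G2/M and mitosis genes. Of its 36 measured members, 25 were higher and 0 lower in the arrays labelled sgNSD3. Adjusted over the list alone, 30 were higher and 1 lower, as at an unadjusted p under 0.05. The median log2 difference was 0.34, with a camera adjusted p of 2.06e-08 and an adjusted p of 0.285 with an estimated correlation. NDC80, of the outer kinetochore, rose by 0.90 (SE 0.088), the spindle checkpoint kinase BUB1B by 0.69 (SE 0.059), the cyclin CCNA2 by 0.58 (SE 0.059) and the microtubule depolymerase KIF2C by 0.49 (SE 0.057) on the log2 scale. The first 3 of these had neighbours that were also higher: their 24 nearest genes had medians of 0.58, 0.40 and 0.34, against 0.07 for KIF2C. With that median subtracted they still passed, at 0.31, 0.29 and 0.25 (limma adjusted p = 0.047, 0.014 and 0.027). The subtraction treats each median as known without error. The list of DNA replication and G1/S genes was not called (camera adjusted p = 0.254). Its 28 measured members held 8 that were higher, among them TYMS at 0.81 (SE 0.063) and PCNA at 0.48 (SE 0.057), and 4 that were lower (8 and 2 with the neighbours' median subtracted), among them GINS2 at -0.46 (SE 0.066). The CDC6 call, among those lower, ended without sgCtrl replicate 1 or 3 or sgNSD3 replicate 3 (limma adjusted p = 0.051 to 0.056) and with the neighbours' median subtracted (0.058). The 24 nearest genes had medians of 0.58 for TYMS, 0.24 for PCNA and -0.21 for GINS2. With these subtracted the genes still passed, at 0.22, 0.24 and -0.25 (limma adjusted p = 0.049, 0.026 and 0.039). Of 14 cyclins and their regulators, 3 were higher and 0 lower (6 and 1 at an unadjusted p under 0.05, 4 and 1 with the neighbours' median subtracted), with CCND2 at 0.61 (SE 0.057; 0.38 with its neighbours' median subtracted) and CDK2 at 0.32 (SE 0.057). That list had a camera adjusted p of 0.245. Its CCNG1 call, also among the p53 targets, ended without sgCtrl replicate 1 or 2 or sgNSD3 replicate 1 or 2 (limma adjusted p = 0.053 to 0.079) and with the neighbours' median subtracted (0.062).

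Transcriptional targets of p53 were called higher in the arrays labelled sgNSD3, with 9 of 16 measured members higher and 0 lower. Adjusted over the list alone, as at an unadjusted p under 0.05, 10 were higher and 0 lower. The median was 0.25, with a camera adjusted p of 0.0022 and an adjusted p of 0.279 with an estimated correlation. GDF15, a stress-induced cytokine, rose by 1.5 (SE 0.11), SESN2 by 0.74 (SE 0.067), TIGAR, which lowers glycolytic flux, by 0.60 (SE 0.065; 0.38 with its neighbours' median subtracted) and AEN by 0.43 (SE 0.071). Apoptosis regulators were called higher too, with 7 of 15 measured members higher and 1 lower (10 and 1 adjusted over the list alone). Their median was 0.23, with a camera adjusted p of 0.0124 and an adjusted p of 0.285 with an estimated correlation. The members that moved act in opposite directions on cell death: the pro-apoptotic BID rose by 0.43 (SE 0.063) and BAK1 by 0.33 (SE 0.065), the anti-apoptotic MCL1 rose by 0.37 (SE 0.061), and the pro-apoptotic BCL2L11 was lower at -0.38 (SE 0.063; -0.63 with its neighbours' median subtracted).

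MYC targets and ribosome biogenesis genes were called higher in the arrays labelled sgNSD3, with 13 of 22 measured members higher and 1 lower (14 and 1 adjusted over the list alone). With the neighbours' median subtracted, 7 were higher and 0 lower, with a median of 0.13, and the list was still called (camera adjusted p = 0.0057). Without that step the median was 0.26, with a camera adjusted p of 0.0039 and an adjusted p of 0.279 with an estimated correlation. The box C/D snoRNP protein NOP58 rose by 0.43 (SE 0.057), nucleolin (NCL) by 0.36 (SE 0.057) and the rRNA methyltransferase NOP2 by 0.34 (SE 0.055). The 24 nearest genes of NCL had a median of 0.33, and with that local median subtracted NCL no longer passed, nor did MRTO4 (limma adjusted p = 0.076). NOP58 and NOP2 were then both at 0.21 and passed. Writers, readers and erasers of histone H3 lysine 36 methylation were called higher with a median of 0.14 (camera adjusted p = 0.0089, adjusted p = 0.392 with an estimated correlation). Only MTF2, a polycomb accessory protein that binds this mark, SMYD2 and PHF19 passed among the 19 measured members, all of them higher, at 0.63 (SE 0.066), 0.26 (SE 0.059) and 0.26 (SE 0.057). Adjusted over the list alone, 3 were higher and 0 lower, and at an unadjusted p under 0.05, 9 and 0. The calls of SMYD2 and PHF19 ended without sgCtrl replicate 1 (limma adjusted p = 0.055 and 0.054) or sgNSD3 replicate 1 (0.057 and 0.052). The 24 nearest genes of MTF2 had a median of 0.30. With the neighbours' median subtracted MTF2 was at 0.33 and passed, and SMYD2 was at 0.19 and did not (limma adjusted p = 0.062). The list's median was then 0.078 and its call ended (camera adjusted p = 0.081).

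Genes of NF-kB signalling, cytokines and the senescence secretome were the weakest call among the higher lists, with a median of 0.11 over 22 measured members and a camera adjusted p of 0.0497 (0.351 with an estimated correlation). NFKB2 at 0.48 (SE 0.070) and the chemokine CCL20 at 0.34 (SE 0.087) were higher and 0 members were lower (1 and 0 adjusted over the list alone, 4 and 0 at an unadjusted p under 0.05, 5 and 0 with the neighbours' median subtracted). The list's call ended without any 1 of sgCtrl replicates 1, 2 and 3 or sgNSD3 replicate 3, at camera adjusted p values of 0.053, 0.066, 0.066 and 0.080. It also ended without the dimmest 25% or 50% of probe sets (0.268 and 0.222), after quantile normalization (0.073) or median centring (0.051), and with a trended variance (0.09995), array weights (0.0502) or the mean of a gene's probe sets (0.055). The CCL20 call ended without any 1 of sgCtrl replicates 1, 2 and 3 or sgNSD3 replicates 1 and 3, at limma adjusted p values of 0.083, 0.071, 0.051, 0.080 and 0.077.

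Genes of cholesterol and fatty acid synthesis were called lower in the arrays labelled sgNSD3, with 11 of 26 measured members lower and 1 higher (13 and 1 adjusted over the list alone). The median was -0.17, with a camera adjusted p of 0.0022 and an adjusted p of 0.351 with an estimated correlation. The fatty acid synthesis enzyme ACACA was at -0.52 (SE 0.056; -0.29 with its neighbours' median subtracted), squalene epoxidase (SQLE) at -0.42 (SE 0.064), the acetate-activating enzyme ACSS2 at -0.39 (SE 0.062) and SREBF2, the transcription factor of the sterol pathway, at -0.37 (SE 0.058).

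Matrix proteases and their inhibitors were called lower, with 8 of 16 measured members lower and 1 higher in the arrays labelled sgNSD3, also when adjusted over the list alone. The median was -0.24 (-0.12 with the neighbours' median subtracted), with a camera adjusted p of 0.0039 and an adjusted p of 0.279 with an estimated correlation. Beside MMP13, cathepsin L (CTSL) was at -1.29 (SE 0.079) and ADAM12 at -0.75 (SE 0.066), whereas ADAM9, a neighbour of NSD3, was higher at 1.25 (SE 0.056). Lysosome and autophagy genes, which share CTSL and CTSB with that list, had 7 of 21 measured members lower and 1 higher (9 and 1 adjusted over the list alone), a median of -0.13 (-0.086 with the neighbours' median subtracted) and a camera adjusted p of 0.0434 (0.479 with an estimated correlation). CTSB was at -0.56 (SE 0.060), as were its 24 nearest genes with a median of -0.55, and no longer passed with that median subtracted. CTSZ was at -0.47 (SE 0.067). The autophagy receptor SQSTM1 was the member that rose, by 0.37 (SE 0.073). The lysosome list's call ended without sgCtrl replicate 1 or 2 or sgNSD3 replicate 2, at camera adjusted p values of 0.053, 0.066 and 0.053. It also ended without the dimmest 25% or 50% of probe sets (0.084 and 0.119) and after quantile normalization (0.059). Targets of TGF-beta and BMP signalling were called lower, with 6 of 12 measured members lower and 1 higher, also when adjusted over the list alone. Their median was -0.25 (camera adjusted p = 0.0232, adjusted p = 0.351 with an estimated correlation). With the neighbours' median subtracted 5 were lower and 1 higher, with a median of -0.18 and a camera adjusted p of 0.0494. With 1 array left out the camera adjusted p ran from 0.016 (sgCtrl replicate 3) to 0.046 (sgNSD3 replicate 2). SKIL, a repressor of SMAD proteins, was at -0.65 (SE 0.059), LTBP1, which binds latent TGF-beta, at -0.63 (SE 0.059) and the BMP antagonist NOG at -0.58 (SE 0.071).

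**Figure D2:**
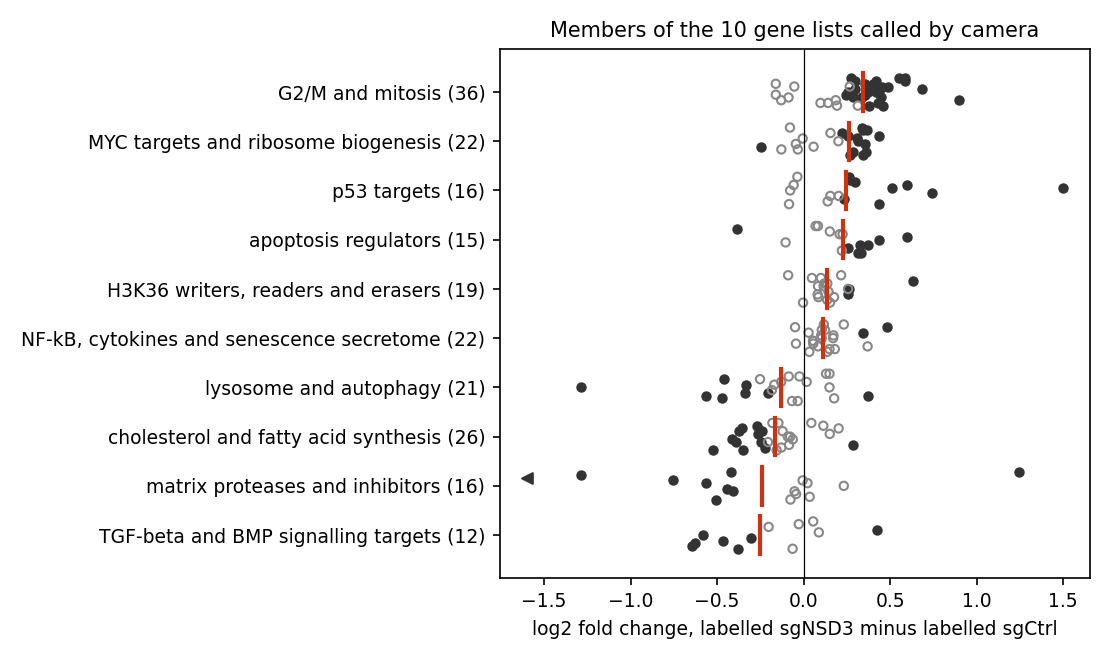
Log2 difference, arrays labelled sgNSD3 minus arrays labelled sgCtrl (x axis), for each measured member of the 10 lists called by camera (y axis, number of members in parentheses). Filled points passed a limma adjusted p of 0.05 over all genes, open points did not, red bars are medians, and the triangle marks MMP13, measured at -3.88, beyond the axis. List medians run from -0.25 for TGF-beta and BMP targets to 0.34 for G2/M and mitosis genes.

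The lists for bone, matrix and YAP and TEAD targets were not called in the main setting, though single members moved far in the arrays labelled sgNSD3. RUNX2, the master transcription factor of osteoblasts, was at -1.62 (SE 0.062), while BMP2 rose by 0.82 (SE 0.068) and osteopontin (SPP1) by 0.77 (SE 0.14). The 24 nearest genes of BMP2 had a median of 0.39, and BMP2 was at 0.43 with it subtracted. Of 18 measured osteoblast genes, 4 were higher and 1 lower (4 and 2 adjusted over the list alone), with a camera adjusted p of 0.633. Of 21 collagen and extracellular matrix genes, 10 were lower and 5 higher (10 and 7 adjusted over the list alone, 10 and 3 with the neighbours' median subtracted), with a camera adjusted p of 0.058. The link protein HAPLN1 was at -2.17 (SE 0.10), lumican (LUM) at -1.85 (SE 0.066), LOXL4, of the collagen cross-linking oxidases, at -1.03 (SE 0.082) and biglycan (BGN) at -1.0 (SE 0.095). Targets of YAP and TEAD had 7 of 14 measured members higher and 3 lower, also when adjusted over the list alone, at a camera adjusted p of 0.058 (counts of 7 and 1 with the neighbours' median subtracted), with WWC1 at 0.83 (SE 0.071) and CRIM1 at 0.77 (SE 0.060). The matrix list was called lower without the dimmest 50% of probe sets (camera adjusted p = 0.0230), with a trended variance (0.0232), without sgNSD3 replicate 1 (0.0453), with the mean of a gene's probe sets (0.0408) and with the neighbours' median subtracted (0.0035). The YAP and TEAD list was called higher with a trended variance (0.0426) and with the neighbours' median subtracted (0.0035).

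Growth factor receptors and their ligands had 8 of 25 measured members higher and 2 lower (8 and 4 adjusted over the list alone) in the arrays labelled sgNSD3, with a camera adjusted p of 0.245. PDGFC rose by 1.51 (SE 0.11), FGF2 by 0.95 (SE 0.061) and EGFR by 0.83 (SE 0.064), whereas ROR1 was at -0.61 (SE 0.095). The FGFR3 call, also among the osteoblast genes, ended without any 1 array but sgNSD3 replicate 2 (limma adjusted p = 0.055 to 0.081). In the MAPK feedback list, 5 of 25 members were higher and 1 lower, also when adjusted over the list alone, at a camera adjusted p of 0.938 (counts of 4 and 4 with the neighbours' median subtracted, at 0.968). EPHA2 rose by 0.75 (SE 0.057) and FOSL1 by 0.74 (SE 0.090), and FOS was at -0.66 (SE 0.10). Notch pathway genes held 4 of 22 higher and 2 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.356). Beside JAG1, the glycosyltransferase LFNG was at -0.91 (SE 0.083) and the co-activator MAML2 at -0.92 (SE 0.11). Among Wnt pathway genes 3 of 23 were higher and 4 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.967), with LGR5 at -0.71 (SE 0.12). The counts were 2 and 2 with the neighbours' median subtracted, where the calls of FZD3 and SFRP1, at 0.83 and 0.38, ended (0.11 for both).

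Genes already tied to NSD3 gave no list call in the main setting. Of 8 genes linked to NSD3 in other tumour cells, 3 were higher and 2 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.949). Of these, ASS1, of arginine synthesis, was at -1.49 (SE 0.070) in the arrays labelled sgNSD3, while EGFR and CDK2 were higher. Of 8 measured NSD3 partners 1 was higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.967). The methyltransferase EHMT2 was at 0.29 (SE 0.060), and BRD3 at -0.41 (SE 0.10) in a stretch where its 24 nearest genes had a median of -0.48. The BRD3 call ended without sgCtrl replicate 2 or sgNSD3 replicate 1 or 3 (limma adjusted p = 0.063, 0.079 and 0.076), and with the local median subtracted BRD3 was at 0.077. Polycomb and chromatin regulators had 4 of 20 higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.517), with CBX6 at 0.54 (SE 0.056). With the neighbours' median subtracted 3 were higher and 0 lower, and the list was called (camera adjusted p = 0.030). EHMT1 then went from -0.43 to -0.087, PCGF2 from -0.29 to -0.055 and ARID1A from 0.39 to 0.20. The calls of these genes ended (limma adjusted p = 0.442, 0.565 and 0.082). HOX genes had 1 of 23 higher and 3 lower, also when adjusted over the list alone, at a camera adjusted p of 0.949 (counts of 3 and 4 with the neighbours' median subtracted, at 0.730), with HOXD10 at -0.63 (SE 0.10) and HOXA2 at -0.59 (SE 0.084).

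Genes that lie near NSD3 on its chromosome differed by side. The genes compared were the nearest with a mean signal of at least 6. Among the 10 that come before NSD3 in gene order, 4 were lower and 0 higher in the arrays labelled sgNSD3, with DDHD2 at -0.61 (SE 0.059). Among the 10 that come after it, 8 were higher and 0 lower, with ADAM32 at 1.85 (SE 0.095), ADAM9 at 1.25 (SE 0.056), TM2D2 at 0.85 (SE 0.070) and FGFR1 at 0.58 (SE 0.057; 0.35 with its neighbours' median subtracted). Of these, ADAM32 was named after its value was seen. The medians of the sides were -0.22 and 0.51, a difference of 0.73 with a permutation p of 0.00079 (100000 resamples, two-sided, across genes, which are not independent). The fixed list of neighbours had 4 of 17 measured members higher and 4 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.808).

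**Figure D3:**
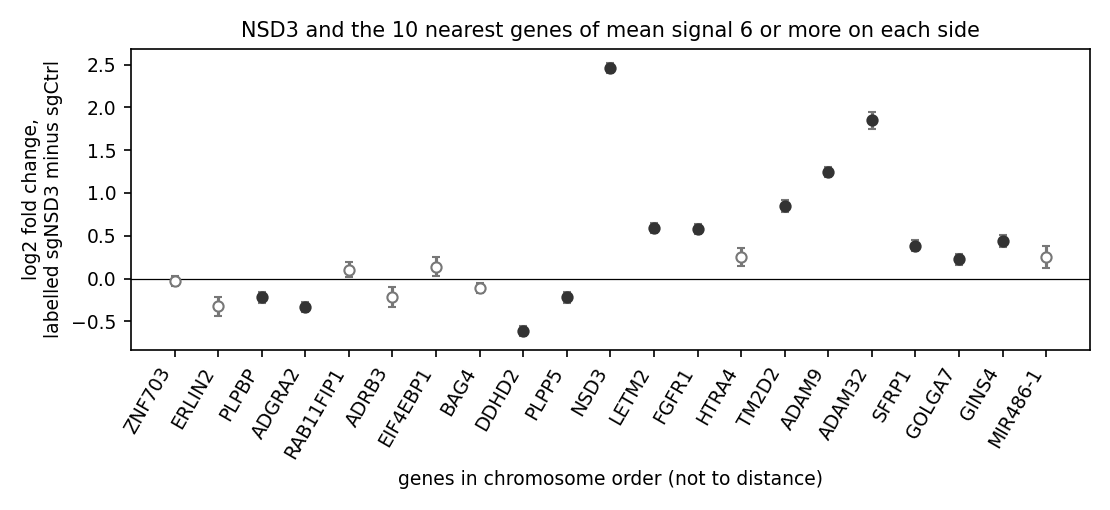
Log2 difference, arrays labelled sgNSD3 minus arrays labelled sgCtrl, with its SE (y axis), for NSD3 and the 10 nearest genes on each side with a mean signal of at least 6, in gene order (x axis, not to distance). Filled points passed a limma adjusted p of 0.05 over all genes, and open points did not. NSD3 is highest at 2.46, the genes after it have a median of 0.51 and those before it a median of -0.22.

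Stress and metabolic lists that were not called in the main setting also held members that passed in the arrays labelled sgNSD3. Since 24.2% of all genes passed, some passing members do not by themselves mark a response of a list. Targets of the unfolded protein response and ATF4 had 6 of 21 members higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.735), with the serine synthesis enzyme PHGDH at 0.80 (SE 0.077) and CTH at -0.61 (SE 0.069). With the neighbours' median subtracted the counts were 6 and 2, and XBP1 went from -0.42 to -0.092 and lost its call. NRF2 targets and metallothioneins had 4 of 14 higher and 0 lower, also when adjusted over the list alone (4 and 1 at an unadjusted p under 0.05; camera adjusted p = 0.315), with MT1E at 0.38 (SE 0.058). The MT2A call ended after median centring (limma adjusted p = 0.061) and without any 1 array but sgCtrl replicate 1 (0.052 to 0.097). Heat shock and proteostasis genes had 4 of 9 higher and 1 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.289), with HSPA1A at 0.34 (SE 0.064). The counts were 4 and 0 with the neighbours' median subtracted, and the HSPH1 call ended after median centring (limma adjusted p = 0.052) and without sgCtrl replicate 2 or 3 or sgNSD3 replicate 1 or 3 (0.076 to 0.101). Hypoxia and glycolysis genes had 4 of 21 higher and 3 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.808), with EGLN3 at 0.33 (SE 0.061) and NDRG1 at -0.33 (SE 0.063). The counts were 2 and 3 with the neighbours' median subtracted, where PGAM1 went from -0.36 to -0.040 and lost its call. The KDM3A call ended without sgCtrl replicate 2 or 3 or sgNSD3 replicate 1 or 3 (limma adjusted p = 0.05005 to 0.058). Oxidative phosphorylation genes had 0 of 11 higher and 2 lower (1 and 2 adjusted over the list alone, and at an unadjusted p under 0.05; camera adjusted p = 0.822). Those lower were COX6C at -0.38 (SE 0.083) and COX7B at -0.21 (SE 0.056). With the neighbours' median subtracted 0 were lower: COX6C did not pass (limma adjusted p = 0.147) and COX7B turned to 0.039. The COX7B call also ended without any 1 array but sgNSD3 replicate 2 (0.083 to 0.105). DNA repair genes had 7 of 21 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.181), with RAD51C at 0.39 (SE 0.063). With the neighbours' median subtracted 3 were higher and 0 lower, and the calls of TP53BP1 (0.54 to 0.18), BARD1 (0.43 to 0.20) and XRCC6 (-0.32 to -0.18) ended (limma adjusted p = 0.071, 0.110 and 0.073).

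Interferon-stimulated genes went both ways, with 5 of 31 higher and 4 lower in the arrays labelled sgNSD3 (5 and 5 adjusted over the list alone; camera adjusted p = 0.949). DDX60 was at 0.67 (SE 0.075) and TRIM22 at 0.66 (SE 0.062), while SAMD9 was at -0.45 (SE 0.066). Antigen presentation genes had 1 of 5 higher and 0 lower (2 and 0 adjusted over the list alone, and at an unadjusted p under 0.05; camera adjusted p = 0.660). The member that passed, TAPBP at 0.21 (SE 0.055), did not pass without any 1 array but sgNSD3 replicate 2 (limma adjusted p = 0.069 to 0.085), after median centring (0.052) or with the neighbours' median subtracted (0.136), where the counts were 0 and 0. Adhesion and integrin genes had 3 of 6 higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.356), with NCAM1 at -0.73 (SE 0.062) and L1CAM at 0.44 (SE 0.085). ALCAM, at 0.46 (SE 0.069), turned to -0.027 with the neighbours' median subtracted. The CD44 call, at 0.26 (SE 0.063), ended after median centring (limma adjusted p = 0.051) and without sgCtrl replicate 2 or 3 or sgNSD3 replicate 1 or 3 (0.058 to 0.075). Genes of the epithelial to mesenchymal transition had 3 of 17 higher and 3 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.967), with the tight junction gene CLDN1 at 1.00 (SE 0.078) and the repressor SNAI2 at -0.59 (SE 0.054). ZEB1, at -0.25 (SE 0.061), lost its call without any 1 array but sgNSD3 replicate 1 (limma adjusted p = 0.053 to 0.077) and was at 0.00054 with the neighbours' median subtracted.

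Markers of 8 other cell types that a culture could hold were not called as lists by camera, which called 0 of them. The lowest camera adjusted p was 0.112, for blood markers, the 1 list of these with an unadjusted p under 0.05. By fry 2 passed, blood markers as higher (fry adjusted p = 0.0018) and chondrocyte markers as lower (0.048). Single markers moved in the arrays labelled sgNSD3. Among 10 blood markers 3 were higher and 1 lower, also when adjusted over the list alone, with LCP1 at 1.78 (SE 0.063), CD68 at 1.40 (SE 0.062) and CD37 at -0.47 (SE 0.10). The LAPTM5 call ended without any 1 array but sgNSD3 replicate 2 (limma adjusted p = 0.052 to 0.065) and with the neighbours' median subtracted (0.168). Among 11 neural markers 1 was higher and 2 lower, also when adjusted over the list alone, with MAP2 at -1.42 (SE 0.064). Endothelial markers held 1 lower of 10, ENG at -1.32 (SE 0.13), and chondrocyte markers 1 lower of 8 (1 higher and 1 lower with the neighbours' median subtracted), MATN3 at -0.69 (SE 0.074). Epithelial markers held 2 higher of 14 (1 adjusted over the list alone, and 1 with the neighbours' median subtracted), KRT18 at 0.57 (SE 0.092) and ESRP1. Adipocyte markers held 1 lower of 9, CD36, and muscle markers 1 higher of 6 (2 adjusted over the list alone), MYF6. The signals of ESRP1, CD36 and MYF6 were below the 25th percentile in both groups. The ESRP1 call ended without any 1 array but sgCtrl replicate 2 (limma adjusted p = 0.076 to 0.124). It also ended after quantile normalization (0.062) or median centring (0.053), and with a trended variance (0.086) or array weights (0.059). The MYF6 call ended without any 1 array but sgNSD3 replicate 2 (0.080 to 0.126), after median centring (0.054) and with a trended variance (0.103). ESRP1 and MYF6, with mean signals under 6, had no neighbours' median to subtract. When it was subtracted from other genes, the log2 differences of ESRP1 and MYF6 did not change. Only their limma adjusted p rose, to 0.059 and 0.054, so that 0 muscle markers passed. Markers of embryonic kidney packaging cells held 2 higher and 1 lower of 9 (2 and 2 adjusted over the list alone), with PAX2 at 0.51 (SE 0.10). The lower one, IGF2BP1 at -0.46 (SE 0.12), did not pass without any 1 array but sgNSD3 replicate 3 (limma adjusted p = 0.061 to 0.095) or with the neighbours' median subtracted (0.151).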

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

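The alternative that subtracts the local median of neighbouring genes was chosen after the data were seen. NSD3 stayed higher in the arrays labelled sgNSD3 and passed under all alternatives run, at log2 differences of 2.34 to 2.67. The count of 3580 genes ran from 2567 to 4230 over the alternatives at the same threshold. It was 2648 with the local median subtracted, of which 2182 were among the 3580, 2172 in the same direction. The count of genes was 1888 at an adjusted p under 0.01. The count at 1.5-fold ran from 610 to 927, with 217 at 2-fold or more, both thresholds stricter by construction. Probe sets past the threshold numbered 2353 at an adjusted p under 0.01, and 3132 to 4154 with 1 array left out, where fewer samples enter. Lists called ran from 8 to 15 over the settings that keep the preset correlation, against 0 with an estimated correlation (5 at an unadjusted p under 0.05) and 24 with fry, which asks another question. With the local median subtracted, 4 lists were gained that no other camera setting called: growth factor receptors and their ligands (adjusted p = 0.030), heat shock and proteostasis (0.049), DNA repair (0.030) and polycomb and chromatin regulators (0.030). Of 156 named genes that passed, 138 kept call and direction in every fit chosen beforehand that included them, and 130 did with the local median subtracted. The stricter adjusted p, the higher fold and the test without moderation were not applied to named genes 1 by 1. The milder and stricter filters on dim probe sets left 151 and 126 of the 156 to test. Genes left out there were not counted as lost. Of the 10 called lists, 7 kept call and direction under all alternatives that keep camera's preset correlation. The share of calls that were higher was 46.0%, 47.8% after quantile normalization and 41.1% after median centring. With the replicate number as a block, 2879 genes, 3239 probe sets and 8 lists passed, and the lysosome and NF-kB lists each had a camera adjusted p of 0.057. The block also ended 11 of the 156 calls of named genes, among them SMYD2 (limma adjusted p = 0.053), PHF19 (0.0502) and CCL20 (0.053). Deviations of same-numbered arrays correlated at -0.02, -0.14 and 0.08, and 1 of 6 arrays correlated best with its own number, so the arrays share only a number and the block's effect is not read as a weaker one.

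With the local median subtracted, 7 named genes changed sign, to 0.077 (BRD3), -0.11 (B2M), -0.027 (ALCAM), 0.00054 (ZEB1), 0.039 (COX7B), -0.0096 (CYC1) and -0.074 (COX5B), as that construction moves each gene by its neighbours. The camera direction also turned in lists that passed in no setting where it turned, and the cause was not tested. Their adjusted p values were 0.984 after median centring and 0.944 with the block for NSD3 partners, and 0.992 without the dimmest 50% of probe sets and 0.806 with the local median subtracted for the neighbours of NSD3. Interferon-stimulated genes had 0.787 without the dimmest 25%, 0.222 without the dimmest 50% and 0.951 with the trended variance. Genes of the epithelial to mesenchymal transition had 0.944 with the block and 0.776 with the local median subtracted. Wnt genes had 0.840 without the dimmest 50% and 0.937 with the trended variance, oxidative phosphorylation 0.979 without the dimmest 50%, and adipocyte markers 0.846 without the dimmest 25%. With the local median subtracted, antigen presentation had 0.776, HOX genes 0.730 and endothelial markers 0.950. With fry, genes linked to NSD3 elsewhere had 0.257 and osteoblast genes 0.771. With 1 array left out, it turned for NSD3 partners without sgCtrl replicate 1 (0.967) or sgNSD3 replicate 2 (0.877), for the epithelial to mesenchymal transition without sgCtrl replicate 3 (0.985) or sgNSD3 replicate 2 (0.877), for Wnt without sgCtrl replicate 2 (0.992) or sgNSD3 replicate 1 (0.944), for interferon-stimulated genes without sgCtrl replicate 1 (0.961) or sgNSD3 replicate 3 (0.923), for endothelial markers without sgCtrl replicate 2 (0.843) and for neural markers without sgNSD3 replicate 2 (0.877). Over all 6 arrays left out in turn, whether the direction turned or not, adjusted p values ran from 0.767 to 0.985 for interferon-stimulated genes, from 0.688 to 0.923 for endothelial and from 0.674 to 0.992 for neural markers.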

Other observations

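The protocadherin beta genes and zinc finger genes were examined as families, and RNA classes compared, after their values were seen. Of the tests on NSD3, all were chosen after the result was seen, as were the covariance test on neighbouring genes, the comparison of the G2/M list with the DNA replication list and the subtraction of the local median.

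Protocadherin beta genes, which encode cell adhesion proteins from a single gene cluster, were examined because PCDHB15, PCDHB18P and PCDHB6 were among the largest falls. Of 19 measured members, 18 were lower and 0 higher in the arrays labelled sgNSD3, also at an unadjusted p under 0.05, with a median log2 difference of -1.47. The signals of 2 members in the arrays labelled sgNSD3, and of 1 in those labelled sgCtrl, were below the 25th percentile, so background limits their differences. Without PCDHB15, PCDHB18P and PCDHB6, 15 of 16 were lower and 0 higher, with a median of -1.36. The median over all 19 was -1.44 after quantile normalization and -1.49 after median centring. A local median exists for 8 members, and their median was -1.69 before and -1.62 after it was subtracted, with all 8 still lower. The family's sequences are similar, and whether probes read each other's transcripts was not analysed here. Of 536 zinc finger genes, 39 were higher and 95 lower, 25% against 24.1% of other genes. That difference did not pass (Fisher's exact p = 0.644, two-sided). At a fold of 2 or more, 4 were higher and 14 lower, 3.36% against 1.39% of other genes (Fisher's exact p = 0.00125, two-sided). Members of this family were already seen among the largest changes when it was chosen, so that p is not independent support.

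Long non-coding RNAs that passed were mostly lower in the arrays labelled sgNSD3, with 142 lower and 61 higher of 1387 measured. Protein-coding genes had 1707 lower and 1519 higher of 11911 (Fisher's exact p for the 2 splits of calls = 2.00e-06, two-sided, across genes, which are not independent). The classes were not matched for signal or size of change, so that p does not establish an effect particular to the class. After quantile normalization 133 long non-coding RNAs were lower and 60 higher, and after median centring 144 and 50. Of 1022 microRNA genes, 34 were lower and 35 higher.

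Fold changes went together along chromosomes. Among 8502 genes with a mean signal of at least 6, taken in RefSeq order, 20 stretches of 10 or more genes had a running median beyond 0.31, which 95% of 1000 shuffled gene orders did not reach, and 8 of them were higher and 12 lower in the arrays labelled sgNSD3. All stretches held 619 genes (7.28%), and 14.9% of the called genes in this order. From TOMM70 to UMPS, 56 genes had a median of 0.52 and 52 of them were above 0. From ZNF76 to SRF, 52 genes had a median of -0.48. Between MTMR9 and CHMP7, 30 genes had a median of -0.64, and between TRIM35 and LEPROTL1, 18 genes had a median of 0.83. These end genes were named after their values were seen.

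NSD3 itself was 5.50-fold higher in the arrays labelled sgNSD3. A single mislabelled array is argued against by the gap of 2.39 log2 units between the lowest array labelled sgNSD3 and the highest labelled sgCtrl, with ranges of 0.08 and 0.09 within the groups. A gain that covers the genes on both sides of NSD3 alike, as the whole cause, is argued against by its 20 nearest genes with a mean signal of at least 6. Their median was 0.18, and none of them reached NSD3 (highest 1.85). That median pools -0.22 before NSD3 and 0.51 after it. It therefore cannot count against a gain that begins at NSD3 or covers NSD3 alone. An exchange of the labels of the groups stays open, since 6 of 6 arrays lay on the side of the other label in both probe sets, and it cannot be told apart from a rise of the NSD3 transcript in cells with the guide, because no sample outside the 2 groups was analysed here. Such a rise was not tested by another method.

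Between the labelled groups, each gene's log2 difference correlated with the median of its 24 nearest genes at a Spearman rho of 0.496 across 8502 genes, against at most 0.044 in 100 shuffled orders. Gene families that lie together are argued against as the cause, since rho was 0.489 without neighbours that share the first 3 letters of the symbol. After quantile normalization rho was 0.497. The arrays' distributions were already close, so that step changed little and cannot count against a cause in the normalization or processing. Noise shared by neighbouring genes on an array was present, with a rho of up to 0.262 when 1 array was set against the others of its group, and may add a part. As the whole cause it is argued against, since the covariance with neighbours between the groups was 48.3 times the highest within a group, scaled to 3 arrays against 3. Differences in chromosome copy number between the cell populations, as could arise when cells are cloned or grown apart, stay open as a hypothesis: rho was still 0.331 with genes 26 to 50 ranks away, but no DNA was measured and an effect of NSD3 on chromatin over long stretches was not tested.

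G2/M and mitosis genes were higher in the arrays labelled sgNSD3, with a median of 0.34. The shift of neighbouring genes is argued against as the cause, since the median was 0.29 with the local median subtracted, 21 of 36 members stayed past the threshold as higher, and the camera adjusted p was 2.08e-09. DNA replication and G1/S genes had a median of 0.07, which goes against an equal rise of all proliferation genes. The permutation p for the difference of medians was 0.00021 (100000 resamples, two-sided, across genes, which are not independent). Estimated correlations between genes were 0.12 in the G2/M list and 0.11 in the DNA replication list, so that p cannot settle the question. The G2/M list's call was lost with an estimated correlation (camera adjusted p = 0.285). A difference in cell cycle phase or growth between the cultures may underlie the shift and was not tested, and its direction depends on the labels that NSD3 puts in doubt.

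Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. Each of the others mixes both labels on each side, so the difference between the labelled groups enters its spread and lowers its counts. Those counts therefore do not show what arrays without a group difference would give. Only 1 split, the real one, gave as many genes, with 3580 against a highest other of 0 by limma (5315 against 611 at an unadjusted p under 0.05). For genes at 1.5-fold or more it was 1 split, with 873 against 0, for probe sets 1 split, with 5288 against 1, and for gene lists 1 split, with 10 against 3.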
